A study of Mus musculus with 6 samples.

How the data were processed

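RNA of 6 cultures of mouse 46C-derived ES cells, 3 with a control vector and 3 with a vector for FLAG-CTCFL, was hybridised to Affymetrix Mouse Gene 1.0 ST arrays after WT terminal labelling of 200 ng total RNA, per the labels' protocols and the design text. These sources speak of 3 biological replicates per condition and of stably transfected cells. The values used were the deposited table of 1 log2 signal per probe set and array; that they are log2 was read from their range of 5.73 to 14.56, and the authors' background correction, summarisation, normalization and software are not given in the sources used here. Array medians lay within 7.92 and 7.99 and the arrays' SDs between 1.41 and 1.47, with the smallest SD in FLAG-CTCFL replicate 2, so the deposited probe set values do not share 1 distribution. Quantile normalization before summarisation is not excluded by this. If the authors' scaling assumed that most genes do not change, an equal shift of all genes would not be seen.

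The table had 34760 probe sets. The platform annotation gave 1 gene symbol to 21640 of them, several to 1321 and none to 11799, and names were updated by Entrez ID through the GRCm38.p6 gene table, which matched 21553 and left 87 with the annotated name. Of several probe sets of a gene the one with the highest mean over all arrays was kept, which left out 1703 and gave 19937 genes. Of the changed genes with more than 1 probe set (352), 4 had probe sets past the threshold in opposite directions (Acer2, Camta1, Cdk12 and U2af1). Gene order along chromosomes came from the same table; no coordinates are given because the arrays' build is not stated. No filter on dim genes was used.

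Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group as the only term, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. Log2 fold changes are FLAG-CTCFL minus control vector, with the moderated SE. In 31 gene lists, fixed with the tests, the rule for named genes and the alternatives before the data were examined, 813 of 950 genes were measured. Lists were tested against all other genes with limma's camera (preset correlation 0.01, Benjamini-Hochberg over lists), with an estimated correlation and with fry as alternatives. Some genes stand on more than 1 list. The median of each chromosome's genes was compared with 100000 random gene sets of the same size. Stretches of neighbouring genes were searched after the data were seen, by circular binary segmentation of the fold changes of genes above the median signal, limited to 1.5 either way, with at least 15 genes per segment, 1000 shuffles and a mean shift of at least 0.2. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

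The rule for named genes took Ctcfl, Ctcf and the architectural and cohesin list; the 15 largest rises and 15 largest falls among changed genes whose arrays do not overlap between groups, passing over unnamed gene models, of which none ranked so high; and, from each list, members past the threshold and up to 4 with the smallest p. Pou5f1, Zfp42, Dazl, Mael, Col3a1, Col1a2 and Vim were named after their values were seen.

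Alternatives were the replicate number as a block, quantile normalization, subtraction of array medians, filters at the 25th and 50th percentile of mean signal, all probe sets, the mean of a gene's probe sets, a variance trend with robust estimation, array weights, an adjusted p of 0.1, a minimum change of 1.5-fold, a t-test per gene without a shared variance, and each array left out in turn. Leaving out the genes of the stretches of lower expression was added after the data were seen. The bounds of the tests of chromosome copies for the stretches and of germ cells were revised after their values were seen, both times to leave more open, and a proteasome family merged by hand after its values were seen, which had passed, was dropped from the test of gene families. Scan dates were not used here, so no batch was tested.

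The procedure was tested on simulated data with the means and moderated variances of the 19937 genes and 200 changed genes. It recovered 92.5% of genes changed by 0.25 on the log2 scale and 100% of those changed by 0.5 or 1. In that simulation 9.72% of calls were false, and over 10 further draws 7.19% on average (3.94% to 8.53%), above the nominal 5%. The data gave 6161 changed genes, many more than the 200 simulated, and the simulated arrays all had the same noise. The recovered and false shares therefore need not hold for the real comparison. The list test called the 1 shifted list alone, and the segmentation recovered 60 of 60 genes of a simulated block. Genes were drawn independently of each other, so the simulation does not test list calls where members are correlated. The chromosome test called 0.4 chromosomes on average with none shifted and 2.6 with 1 chromosome shifted by 0.1, which it found in 10 of 10 draws, so small shifts of other chromosomes can follow from a real shift of 1.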

Results

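Gene expression was measured in mouse embryonic stem (ES) cells derived from 46C, a male line of 129P2/OlaHsd background that carries a GFP reporter in the Sox1 gene. Cells were transfected with an expression construct for FLAG-tagged mouse CTCFL or with its control and were kept in medium with 10% serum under 1 µg/ml puromycin. CTCFL, also called BORIS, is a paralog of the insulator-binding protein CTCF and is normally found in male germ cells. Total RNA of 3 replicates per group, 6 in all, was read on 1-colour Affymetrix Mouse Gene 1.0 ST arrays, and values are given as log2 signal. Array medians lay between 7.92 and 7.99. Pearson's r over the tested genes was 0.9983 to 0.9986 within the control group, 0.9969 to 0.9981 within the FLAG-CTCFL group and 0.9826 to 0.9849 between groups, and the first principal component, with 82.9% of the variance, separated the groups. The number of arrays limits the precision, and the labels do not tell how many independently transfected lines each group holds, so p-values measure only the spread between these arrays.

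The comparison asked which transcripts differ in ES cells that make CTCFL, in a series concerned with CTCFL, CTCF and cohesin at promoters. Ctcfl itself was read first, since it checks the labels. Its log2 signal was 7.70, 7.85 and 7.89 in the control arrays and 11.33, 11.22 and 11.24 in the FLAG-CTCFL arrays, a rise of 3.45 ± 0.05 (SE, n = 3 per group; 10.9-fold; limma adjusted p = 6.15e-13). Ctcf differed by 0.01 ± 0.05 (adjusted p = 0.880). Of the core cohesin subunits, Smc1a (0.12 ± 0.05, adjusted p = 0.0846), Smc3 (-0.01), Rad21 (0.08) and Stag2 (0.12) did not pass the test, and Stag1, the alternative to Stag2 in the ring, rose by 0.39 ± 0.05 (adjusted p = 5.67e-05). After quantile normalization of the arrays Smc1a, Rad21 and Stag2 passed as well, at 0.19, 0.16 and 0.21, and Smc1a and Stag2 also passed without FLAG-CTCFL replicate 2, at 0.17 and 0.19, and with array weights (adjusted p = 0.00253 and 0.00390). The cohesin loader Nipbl (-0.06) did not pass, while the release factor Wapl fell by 0.18 (adjusted p = 0.0252), a call lost after quantile normalization (adjusted p = 0.0605), after subtraction of array medians (0.0872), without a variance shared between genes (0.177) and without control replicate 1 (0.0584) or 2 (0.128) or FLAG-CTCFL replicate 2 (0.0706). In the list of architectural proteins and somatic cohesin, 3 of 28 measured genes were higher and 8 lower, with the same counts when adjusted over the list alone, and the list did not pass as a set (camera adjusted p = 0.546). The balance turned after quantile normalization, with 9 higher and 5 lower, and without FLAG-CTCFL replicate 2, with 7 and 4 (median 0.03 against -0.04), so it depended on that array. After subtraction of array medians 3 were higher and 4 lower, and outside the stretches of lower expression 3 of 25 were higher and 5 lower. Its largest falls were in Esco2, an acetyltransferase of Smc3 (-0.78), in Hdac8, the enzyme that removes that mark (-0.56), and in the condensin subunit Ncapd2 (-0.42). These 3 genes lay in the stretches of lower expression on chromosomes 14, X and 6 that are described with the chromosomes.

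Mest, a paternally expressed imprinted gene, rose more than any other gene, from 7.76 ± 0.09 to 11.50 ± 0.25 (SD, n = 3), by 3.74 ± 0.10 on the log2 scale (SE; adjusted p = 3.08e-11). After Ctcfl followed Stra8, a gene of meiotic entry (2.34), and the X-linked Rhox13 (2.20), Ct55 (2.19), Scml2 (2.001) and Nxf3 (1.78), all known from the testis. Dnajc5g (1.86), Peg10, a paternally expressed gene of retrotransposon origin (1.78), Asz1, a gene of the piRNA pathway (1.68), Car4 (1.63), Crygd (1.599), Wfdc15a (1.57), Irak3 (1.55) and Adgrl2 (1.44) completed the 15 largest rises. The control means of Dnajc5g (7.28) and Wfdc15a (7.60) lay below 7.63, the 95th percentile of olfactory and vomeronasal receptor genes, so their rises are lower bounds. Sfrp1, which codes for a secreted Wnt antagonist, fell by 2.41 ± 0.05 on the log2 scale (SE; adjusted p = 7.06e-12), more than any other gene, from 11.61 ± 0.10 to 9.20 ± 0.04 (SD, n = 3). Grb10, an imprinted adaptor of the insulin receptor, fell by 2.34. Klhl13 (-2.12), Serpinb6c (-1.92), the claudin gene Cldn4 (-1.87), Igfbp7 (-1.78), Myof (-1.72) and Fxyd6 (-1.64) lay outside the stretches of lower expression, and Uprt (-2.14) in that on chromosome X, Ndrg2 (-2.13), Trim13 (-2.04) and Ephx2 (-1.85) in that on chromosome 14, and Emp1 (-1.95), Ldhb (-1.76) and A2m (-1.64) in that on chromosome 6. Adjusted p was at most 3.66e-08 for these 30 genes.

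**Figure D1:**
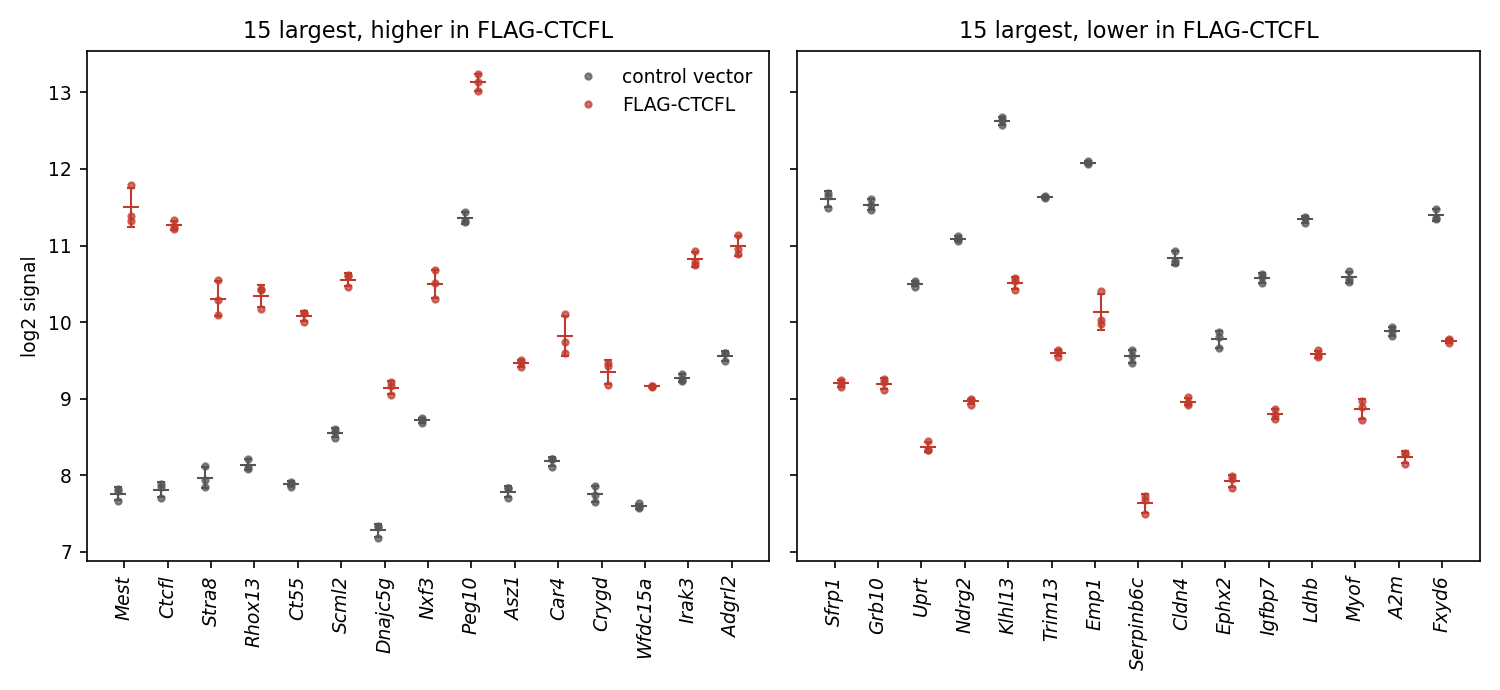
Log2 signal of the 15 genes with the largest rise (left) and the 15 with the largest fall (right) in FLAG-CTCFL against control vector arrays. Points are single arrays, horizontal marks the mean and bars the SD of 3 arrays; for each gene all 3 arrays of one group lie above all 3 of the other, and Mest moves from a mean of 7.76 to 11.50.

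Of 19937 genes tested, 6161 changed (30.9%), 2496 higher and 3665 lower in FLAG-CTCFL cells. Most changes were small: 709 genes changed at least 1.5-fold, 157 higher and 552 lower, and 161 at least 2-fold, 42 higher and 119 lower. The 3 arrays of one group lay above all 3 of the other for 41.3% of genes, where chance gives 10%. The balance of directions depended on the scaling of the arrays: 40.5% of the changed genes were higher with the deposited values, and 54.4% (3943 higher and 3306 lower) after quantile normalization. The median log2 fold change over all genes was 0.0037 as deposited and 0.0099 after quantile normalization. Outside the stretches of lower expression on chromosomes 6, 14 and X, 2469 genes were higher and 3186 lower, and 153 against 356 at least 1.5-fold.

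**Figure D2:**
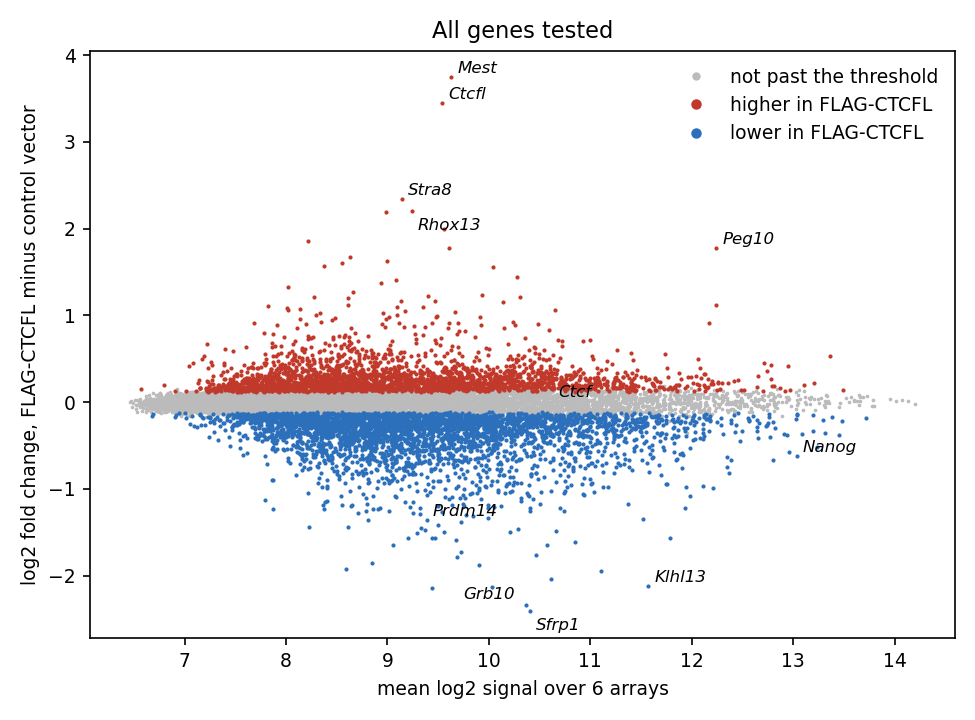
Log2 fold change (FLAG-CTCFL minus control vector) of 19937 genes against their mean log2 signal over the 6 arrays, with red for the 2496 genes past the threshold and higher, blue for the 3665 lower and grey for the others. Mest (3.74) and Ctcfl (3.45) stand above all other genes, and Sfrp1 (-2.41) and Grb10 (-2.34) lie lowest.

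Genes of the germ line rose more often than they fell. Of 44 measured germ line and cancer-testis genes 22 were higher and 8 lower (24 and 10 adjusted over the list alone), with a median log2 fold change of 0.14 (camera adjusted p = 0.000271, and adjusted p = 0.389 with an estimated correlation). Beyond Rhox13 and Asz1, rises were seen for Prss50 (1.37), Tuba3b (1.33), Slc25a31, a germ cell ADP/ATP carrier (1.17), and the piRNA pathway genes Gtsf1 (1.12), Tex19.1 (0.98) and Mov10l1 (0.79). The germ cell RNA helicase Ddx4 rose by 0.28, whereas Dazl (0.06) and Mael (-0.08) did not pass. Prdm1 (-0.98), Tdrd12 (-0.87), Rnf17 (-0.82) and Tex14 (-0.64) fell, and Rnf17 is 1 of 3 falling members in a stretch of lower expression. Of 22 genes of meiotic cohesin and the synaptonemal complex 10 were higher and 4 lower, also when adjusted over the list alone, without passing as a set (camera adjusted p = 0.0927). Stra8 (2.34), Sycp2 (0.65), Mei4 (0.61) and the meiotic cohesin subunit Rec8 (0.42) rose, while Sycp3, of the axial element (-1.21), Smc1b, a meiotic cohesin subunit (-0.69), and Syce2 (-0.61) fell. Rec8 rose although it lies in the stretch of lower expression on chromosome 14.

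Genes of the 2-cell-like state, a rare state of ES cultures that resembles the early embryo, were higher, with only 14 of the 36 listed genes measured. Of these, 10 were higher and 1 lower (10 and 1 adjusted over the list alone), and the median was 0.47 (camera adjusted p = 6.79e-05, and adjusted p = 0.573 with an estimated correlation). Zfp352 (0.88), Tdpoz2 (0.87) and Tdpoz3 (0.63) rose, as did the Usp17l family members Usp17lc (0.57), Usp17lb (0.56, at adjusted p = 0.0619 without a variance shared between genes) and Usp17la (0.55). The Usp17l and Tdpoz genes are families of near-identical copies, so their values are not independent. Eif1a fell by 0.27. Of the lists of other cell types that a culture could hold, the medians were 0.04 for trophoblast, 0.07 for fibroblasts, 0.03 for mesoderm, 0.01 for neural ectoderm and 0.0011 for endoderm. With 1 array left out they were 0.03 to 0.06 for trophoblast, 0.04 to 0.10 for fibroblasts, 0.01 to 0.06 for mesoderm, -0.00060 to 0.04 for neural ectoderm and -0.0052 to 0.03 for endoderm.

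Genes of naive and general pluripotency fell more often than they rose. Of 37 measured genes of naive and general pluripotency 21 were lower and 2 higher (22 and 2 adjusted over the list alone), with a median of -0.23 (camera adjusted p = 1.81e-07, and adjusted p = 0.573 with an estimated correlation). Prdm14, a repressor that stabilises the naive state, fell by 1.36, Tcl1 by 1.17, Tfcp2l1 by 0.98, Fgf4 by 0.94 and Nr5a2 by 0.84. Smaller falls were measured for Esrrb (-0.50), Klf2 (-0.48), Klf4 (-0.35) and Sox2 (-0.21). Pou5f1 (-0.11) and Zfp42 (-0.12) did not pass, and Dnmt3l (0.40) and Sall4 (0.21) rose. Nanog (-0.62), Gdf3 (-0.63) and Nr0b1 (-0.99) fell too and lie in the stretches of lower expression on chromosomes 6 and X; without such genes 18 of 33 members were lower and 2 higher, with a median of -0.21 (camera adjusted p = 1.04e-06, and adjusted p = 0.716 with an estimated correlation).

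Genes of formative and primed epiblast moved both ways, with 6 of 21 higher and 8 lower (6 and 11 adjusted over the list alone; camera adjusted p = 0.289). Pim2 (1.21), Lef1 (0.40), Tcf15 (0.38), Otx2 (0.32) and Fgf5 (0.21) rose, and the tight junction genes Cldn6 (-1.497) and Ocln (-0.54), Grhl2 (-0.58) and Dnmt3a (-0.53) fell. Among trophoblast genes 8 of 24 were higher and 2 lower, the same adjusted over the list alone (median 0.04; camera adjusted p = 0.0308, and adjusted p = 0.573 with an estimated correlation). This call was lost after quantile normalization (adjusted p = 0.0967; median 0.05), without genes under the median signal (0.0953; median 0.16) and without control replicate 1 (0.0745; median 0.03), and the median was 0.0626 without control replicate 3 and 0.0584 without FLAG-CTCFL replicate 1. Krt8 (1.15) and Krt18 (1.04), keratins of simple epithelia that were also on the adhesion list, Eomes (0.61), Gata3 (0.33) and Cdx2 (0.30) rose, and Tfap2c (-0.73) and Ets2 (-0.60) fell. The other lineage lists did not pass. In neural ectoderm 4 of 31 genes were higher and 6 lower (camera adjusted p = 0.642), among them Nes (0.68), Sox11 (0.37), Elavl3 (-0.64) and Map2 (-0.44). In primitive streak and mesoderm 6 of 27 were higher and 1 lower (0.123), with Eomes, Wnt8a (0.52) and Mixl1 (0.31) higher and Bmp4 (-1.26), which lies in the stretch on chromosome 14, lower. In endoderm 8 of 30 were higher and 5 lower (0.508), with Lrp2 (0.86) and Pdgfra (0.54) higher and Nid1 (-1.46) and Apoe (-0.95) lower. Among fibroblast genes, listed because feeder cells could contribute RNA, 6 of 28 were higher and 5 lower (7 and 5 adjusted over the list alone; camera adjusted p = 0.469). Timp3 (-0.79), Fstl1 (-0.73) and Thy1 (-0.48) fell, Thbs1 (0.54) rose, and Col3a1 (0.06), Col1a2 (0.11) and Vim (-0.03) did not pass. Counts adjusted over the list alone were the same for neural ectoderm, mesoderm and endoderm.

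Imprinted genes changed in both directions, with more of them higher. Of 45 measured, 19 were higher and 9 lower (19 and 10 adjusted over the list alone), with a median of 0.05 (camera adjusted p = 0.0248, and adjusted p = 0.416 with an estimated correlation). Besides Mest and Peg10, Sgce, a neighbour of Peg10 (1.05), Meg3, a maternally expressed long non-coding RNA (1.06), H13 (0.86), Igf2 (0.65) and Nnat (0.64) rose, and besides Grb10, Phlda2 (-0.97), Ddc, a neighbour of Grb10 (-0.65), and Dio3 (-0.47) fell. The set call was lost after quantile normalization (adjusted p = 0.0760; median 0.05) and after subtraction of array medians (adjusted p = 0.0556; median 0.07). The median was 0.0250 without FLAG-CTCFL replicate 2, 0.0756 without FLAG-CTCFL replicate 1 and 0.21 without genes under the median signal. Few genes of other clusters known to be bound by CTCF, the Hox and protocadherin genes, passed the threshold. Neither list gave a set result without genes under the median signal. The protocadherin list also gave none without genes under the 25th percentile of mean signal. Of all genes in the dimmest class by mean signal 2.91% changed, and of the next class 13.1%. Dim signal may therefore hide changes, and the few calls do not show that these clusters were unaffected. Of 37 Hox genes 1 was higher, Hoxb1 (0.13, a call lost without control replicate 1 or 2 or any single FLAG-CTCFL array, at adjusted p between 0.0557 and 0.157, with the replicate block, at 0.0645, and without a variance shared between genes, at 0.0844), and 2 lower, Hoxc12 (-0.39, at adjusted p = 0.0636 without a shared variance) and Hoxc13 (-0.17), with 0 and 2 adjusted over the list alone (camera adjusted p = 0.493). None of the 22 measured clustered protocadherin genes, all of the beta cluster, passed limma's test in either adjustment (median 0.03; camera adjusted p = 0.392). With array weights Pcdhb4 (0.11, adjusted p = 0.0143), Pcdhb7 (0.11, adjusted p = 0.00989) and Hoxd13 (0.13, adjusted p = 0.00414) passed. Of 8 Y-linked genes 2 were higher and 3 lower, also adjusted over the list alone (camera adjusted p = 0.537), with Kdm5d (0.36) and Usp9y (0.26) higher and Zfy1 (-1.06), Uba1y (-0.47) and Uty (-0.41) lower. The control means of the 2 higher genes (7.38 and 7.26) lay in the background range. Without genes under the median signal the list median was -0.44 against -0.06 (camera adjusted p = 0.110).

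Genes of glycolysis and of cholesterol synthesis fell. Among genes of glycolysis and hypoxia 16 of 28 were lower and 2 higher (17 and 3 adjusted over the list alone), with a median of -0.21 (camera adjusted p = 1.71e-05, and adjusted p = 0.389 with an estimated correlation). Egln3, a prolyl hydroxylase induced by hypoxia (-1.36), the mitophagy receptor Bnip3 (-0.98), Aldoc (-0.88), Ndrg1 (-0.78) and Vegfa (-0.71) fell, and so did Tpi1 (-0.81), Bnip3l (-0.76), Pgk1 (-0.57) and Slc2a3 (-0.36), which lie in the stretches of lower expression. Outside these, 12 of 24 were lower and 2 higher, with a median of -0.14 (camera adjusted p = 0.000631, and adjusted p = 0.416 with an estimated correlation). Among genes of cholesterol synthesis 14 of 20 were lower and 1 higher (15 and 2 adjusted over the list alone), with a median of -0.22 (camera adjusted p = 1.71e-05, and adjusted p = 0.573 with an estimated correlation). Falls were measured for Srebf2, the transcription factor of the pathway (-0.52), Insig1 (-0.55), Idi1 (-0.42), Hmgcs1 (-0.37) and Cyp51 (-0.37), and for Nsdhl (-0.95) and Fdft1 (-0.82), which lie in the stretches on chromosomes X and 14. After quantile normalization 12 of the list were lower and 2 higher, with a median of -0.15.

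Feedback genes of FGF-ERK signalling rose, with 11 of 17 higher and 3 lower (11 and 4 adjusted over the list alone) and a median of 0.15 (camera adjusted p = 0.0248, and adjusted p = 0.573 with an estimated correlation). Dusp4 (0.60), Etv4 (0.58), Dusp6 (0.49) and Dusp5 (0.47) rose, and Il17rd (-0.47) and Ccnd1 (-0.43) fell. The set call was lost after subtraction of array medians (adjusted p = 0.0556; median 0.17) and without genes under the median signal (adjusted p = 0.0675; median 0.15). After quantile normalization the median was 0.22. Fewer genes were higher without control replicate 2 (7 higher and 3 lower) or control replicate 3 (7 and 2). Among Nodal, activin and BMP targets 5 of 20 were higher and 10 lower (6 and 11 adjusted over the list alone; median -0.17; camera adjusted p = 0.0937), and outside the stretches of lower expression 5 of 17 were higher and 7 lower (median 0.01; camera adjusted p = 0.544). The Nodal targets Lefty2 (-1.57) and Lefty1 (-0.85) and the inhibitor Smad7 (-0.84) fell, Dusp9 (-1.17) fell within the stretch on chromosome X, and the BMP targets Id1 (0.55), Id2 (0.55) and Id3 (0.53) rose. Of 19 Wnt targets 8 were higher and 3 lower, the same adjusted over the list alone (camera adjusted p = 0.0673), including Lef1 (0.40), Apcdd1 (0.29) and Axin2 (0.28). Without control replicate 1, 4 Wnt targets were higher and 2 lower. Immediate-early genes went both ways, with 7 of 25 higher and 8 lower in both adjustments (camera adjusted p = 0.642), led by Ccn1 (1.23), Ccn2 (0.93), Atf3 (0.71), Nr4a1 (-0.76) and Zfp36 (-0.66).

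Genes of cell adhesion and extracellular matrix fell more often than they rose, with 18 of 35 lower and 10 higher (19 and 11 adjusted over the list alone) and a median of -0.18 (camera adjusted p = 0.0248, and adjusted p = 0.573 with an estimated correlation). Epithelial adhesion genes Cldn4 (-1.87), Epcam (-1.17), Cldn7 (-0.84), Cldn3 (-0.44) and Cdh1 (-0.38) fell, as did the integrin gene Itgb5 (-0.88), and Lgals3 (-1.48) fell within the stretch on chromosome 14. Krt8, Krt18, Itga5 (0.41) and Agrn (0.41) rose. Without genes in the stretches of lower expression this call was lost, with 15 of 32 lower and 10 higher and a median of -0.09 (camera adjusted p = 0.0748), and it was lost without genes under the median signal (adjusted p = 0.0827), where the median was larger at -0.36, and with array weights (adjusted p = 0.0590; median -0.19). After quantile normalization the median was -0.12.

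**Figure D3:**
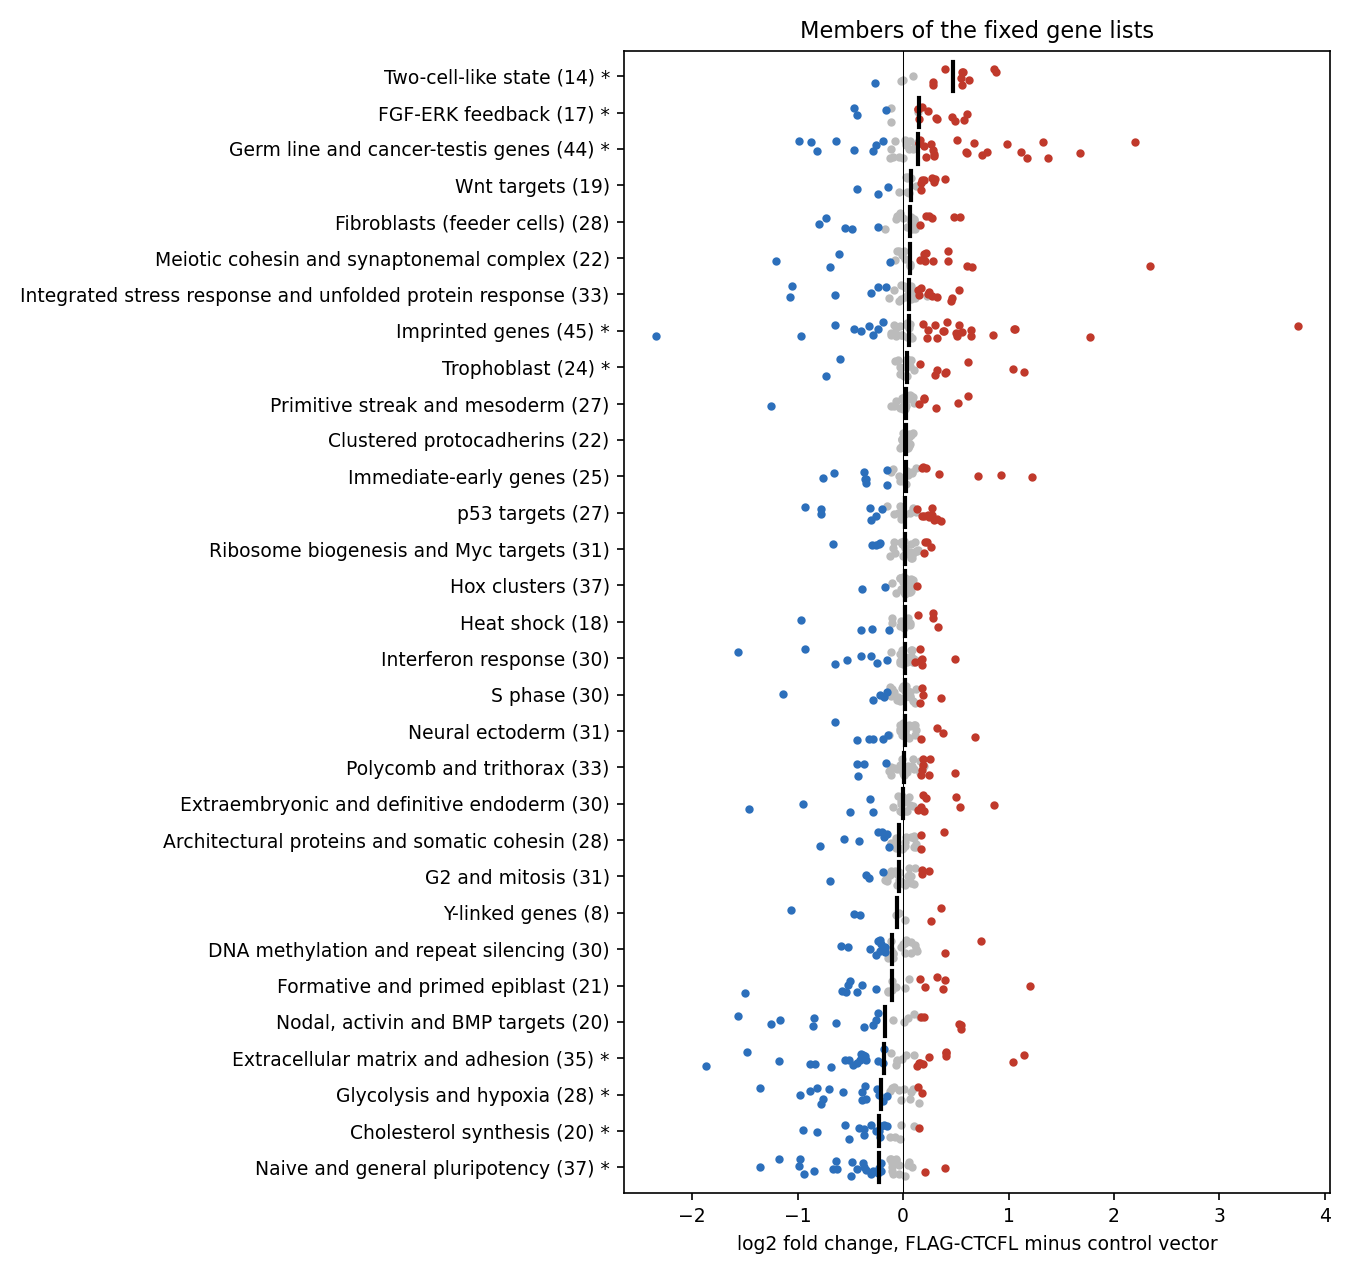
Log2 fold change (FLAG-CTCFL minus control vector) of each measured member of 31 gene lists, with the number measured in brackets; red points are past the threshold and higher, blue lower, grey not past, and black bars are list medians. An asterisk marks the 9 lists past the threshold in camera with a preset correlation, from the 2-cell-like state with a median of 0.47 at the top to pluripotency with -0.23 at the bottom.

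The remaining lists did not pass as sets. Interferon response genes included clear falls, Ifitm1 (-1.57), Ifitm3 (-0.93) and Xaf1 (-0.64), against a rise of B2m (0.49), with 6 of 30 higher and 8 lower (camera adjusted p = 0.804). Of p53 targets 10 of 27 were higher and 7 lower (11 and 8 adjusted over the list alone; camera adjusted p = 0.642), with Perp (-0.93), Plk2 (0.36) and Mdm2 (0.20) among them. In the integrated stress and unfolded protein responses 10 of 33 were higher and 6 lower (11 and 6 adjusted over the list alone; camera adjusted p = 0.182), with Mthfd2 (0.53), Sdf2l1 (0.47) and Atf4 (0.46) higher and Ero1a (-1.05) and Slc7a3 (-1.08) lower, both of them in stretches of lower expression. Heat shock genes had 4 of 18 higher and 4 lower (0.971), led by Hspb8 (-0.97), and ribosome biogenesis genes 4 of 31 higher and 5 lower (0.642), led by Dkc1 (-0.67) on chromosome X. Cell cycle lists moved little: 4 of 30 S phase genes were higher and 5 lower (0.928), led by Pola1 (-1.14) in the stretch on chromosome X, and 3 of 31 genes of G2 and mitosis were higher and 4 lower (0.603), led by Dlgap5 (-0.69) in that on chromosome 14. In DNA methylation and repeat silencing 2 of 30 were higher and 10 lower (2 and 11 adjusted over the list alone; camera adjusted p = 0.182), with Mbd3 (0.74) higher and Dnmt3a (-0.53), Tet1 (-0.24) and Atrx (-0.59, on chromosome X) lower. Its counts were 2 and 18 without FLAG-CTCFL replicate 1 (median -0.17) and 6 and 9 without FLAG-CTCFL replicate 2 (median -0.05). Of Polycomb and trithorax genes 7 of 33 were higher and 4 lower (8 and 4 adjusted over the list alone; camera adjusted p = 0.445), with Kmt2a (0.49) higher and Ezh1 (-0.44) and Mtf2 (-0.43) lower. Counts adjusted over the list alone were the same for the interferon, heat shock, ribosome, S phase and G2 lists. Median and mean differed in sign for the endoderm, fibroblast, p53, ribosome, S phase, heat shock and interferon lists, none of which passed. In all, 9 of 31 lists passed, 5 of them higher and 4 lower, and 0 with an estimated correlation, where the smallest adjusted p was 0.389; at an unadjusted p, 3 of these reached the threshold, the germ line (p = 0.0251), glycolysis (p = 0.0143) and imprinted lists (p = 0.0403). Fry called 14 lists as moving one way. Further lists passed camera with 1 array left out: without FLAG-CTCFL replicate 1 the DNA methylation (adjusted p = 0.0188), Wnt (0.0344), mesoderm (0.0420) and Nodal lists (0.0460), without control replicate 2 the meiotic list (0.0498), and without control replicate 3 the Wnt list (0.0207). With all arrays and an estimated correlation in camera, these lists had adjusted p between 0.573 and 0.908. Without genes in the stretches of lower expression the Wnt (0.0393) and stress response lists (0.0471) passed, both higher, at adjusted p = 0.765 and 0.834 with an estimated correlation. After quantile normalization more genes were higher than lower in the S phase (11 and 3), G2 (8 and 3), ribosome (11 and 5) and immediate-early lists (9 and 7), against the balance with the deposited values, and the counts were 6 and 8 for DNA methylation (median -0.05 against -0.11) and 13 and 3 for Polycomb (median 0.07 against 0.01). The balance also turned without FLAG-CTCFL replicate 2 for the ribosome (9 and 5) and G2 lists (5 and 3), without FLAG-CTCFL replicate 1 for Polycomb (6 and 7), without control replicate 1 or after subtraction of array medians for immediate-early genes (7 and 6), and with array weights for the ribosome (11 and 7), S phase (8 and 7), neural (8 and 7), Hox (5 and 3) and interferon lists (9 and 8).

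Expression of brighter genes was lower along stretches of 3 chromosomes. Among the brighter genes, those above the median of mean signal, 199 genes in a stretch of chromosome 14 from Tspan14 to Tdrd3 had a median log2 fold change of -0.55, with 94.97% of them below 0. A stretch of chromosome X from Mcf2 to Tspan6 (127 genes) had a median of -0.63 with 94.5% below 0, and a stretch of chromosome 6 from Bhlhe40 to C2cd5 (149 genes) a median of -0.33 with 91.3% below 0. Each stood at about that level in every FLAG-CTCFL array, with array medians against the control mean of -0.52 to -0.58 on chromosome 14, -0.61 to -0.71 on chromosome X and -0.29 to -0.39 on chromosome 6, while control arrays lay between -0.02 and 0.01. The 3 stretches held 1073 tested genes, of which 479 were lower and 27 higher, and 35.5% of all genes that fell at least 1.5-fold. Over all 1073 genes the median was -0.08. The dimmer genes of the stretches had medians of -0.0027 on chromosome 14 (226 genes), -0.014 on chromosome X (153) and -0.0050 on chromosome 6 (219). A shorter stretch of chromosome 12 from Eml1 to Mir485 (19 genes), which holds the imprinted Dlk1, Meg3 and Rian, was higher with a median of 0.32. Every other gene of it is fewer than the 15 that a segment needs, so it had no check on genes left out of the search. Leaving out the stretches of lower expression kept these genes, so the imprinted list was not tested without them. Gene order was taken from the GRCm38.p6 annotation. In the test of whole chromosomes, across genes, which are not independent replicates, 6 of 21 passed: chromosomes 14 (median of all its genes -0.05) and X (-0.02), both at an adjusted p of 0.000105 from the smallest p that the random gene sets can give, and 5, 6, 11 and 15, with medians between -0.01 and 0.02. Among the brighter genes alone 8 chromosomes passed the same test. Chromosome 5 was lost (adjusted p = 0.108), and chromosomes 8 (0.0211), 13 (0.0332) and 17 (0.0444) were gained, so the chromosomes with small shifts depended on the dim genes. Over all genes but those of the 3 stretches, a setting chosen after the data were seen, chromosomes 14 (adjusted p = 0.686) and X (0.380) no longer passed. Only chromosome 9 passed there, with a median of -0.0033.

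**Figure D4:**
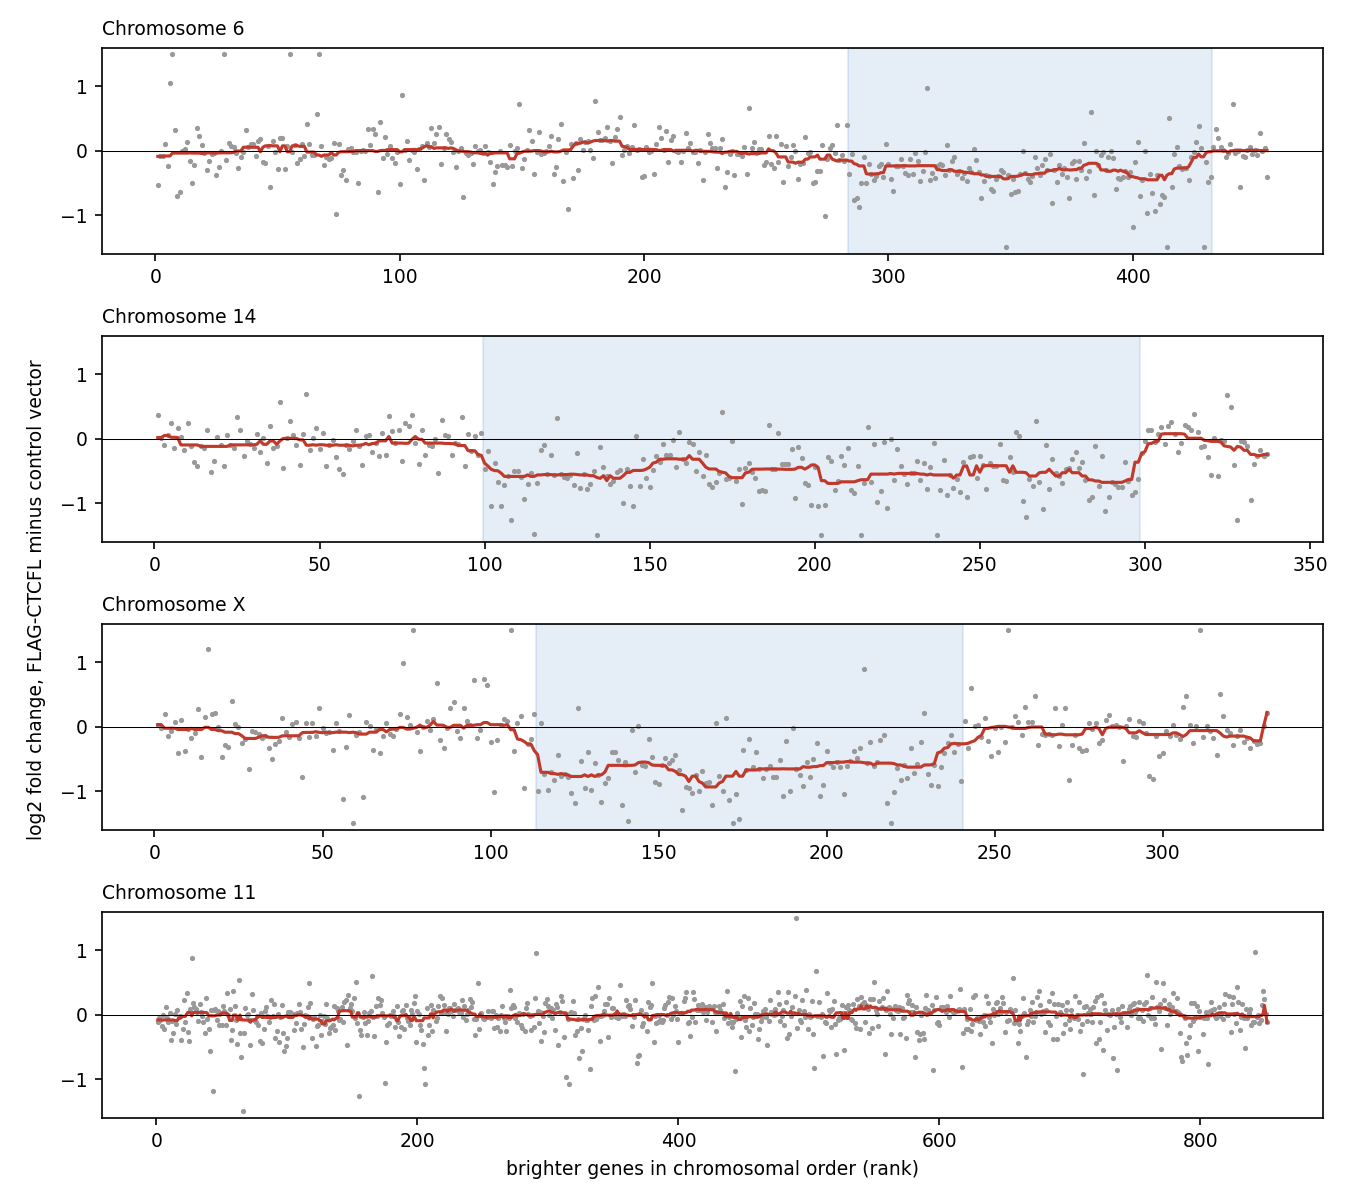
Log2 fold change (FLAG-CTCFL minus control vector) of genes above the median signal in chromosomal order on chromosomes 6, 14 and X, and on chromosome 11 for comparison. Grey points are single genes, drawn at 1.5 or -1.5 where they lie beyond, the red line is a running median, and shading marks the stretches with medians of -0.33, -0.55 and -0.63.

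Changes were most frequent among well expressed genes. With genes ranked by mean signal in 5 equal classes, from the dimmest to the brightest, 2.91%, 13.1%, 38.2%, 53.6% and 46.7% changed. Lower genes made up 1.00% of the dimmest class, 33.2% of the fourth and 30.2% of the brightest, and higher genes 1.91%, 20.4% and 16.5%. Olfactory and vomeronasal receptor genes, 1194 genes that ES cells are not known to use, had a median log2 signal of 7.09, close to the median of 7.19 of the dimmest class, so changes there were hardly measurable. This set was chosen after the data were seen. Its 95th percentile of 7.63 lay above the control means of Tuba3b (7.35), Sycp2 (7.62), Nnat (7.54), Cdx2 (7.56) and Kdm5d (7.38), so their rises are lower bounds as well. Usp9y lay below it in both groups (7.26 in control and 7.53 in FLAG-CTCFL arrays), so its rise may lie within the background. The same holds for Tex12 (7.06 and 7.48), Lgr5 (7.38 and 7.55), Ifi27 (7.47 and 7.58), Ifih1 (7.39 and 7.56) and Tnc (7.40 and 7.53), which passed as higher. It also holds for Meiob (7.01 and 6.88), which passed as lower. List counts that include these genes are uncertain to that extent.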

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

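The tests of the stretches of lower expression and of germ cells were chosen after the result was seen; the tests of other splits, of array normalization and chromosome copies for the many changed genes, of general loss of silencing and of other cell types were set before.

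Signals also differed in probe sets that the comparison of named genes did not use. Among probe sets with several gene symbols, 11 passed the threshold and were at least 2-fold higher in FLAG-CTCFL cells and 2 at least 2-fold lower, with log2 fold changes between -1.15 and 2.14. Among those with no symbol 8 were higher and 14 lower, between -2.04 and 1.85.

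Many genes of small fold passed the threshold. Quantile normalization argues against the scaling of the arrays as the whole source, since 91.3% of the changed genes passed again in the same direction, though the share of higher genes moved. Different chromosome copies are argued against as the whole direct source, since 5655 of 18864 genes outside the 3 stretches of lower expression changed. Inside them 506 of 1073 genes changed. Of the changed genes 91.8% lie outside the stretches. By chromosome, 89.995% of the changed genes lie on those whose brighter genes have a median shift under 0.1, chromosome 6 (-0.07) among them. Both shares largely follow from where the tested genes lie. Changes elsewhere that follow from the dosage of genes within the stretches were not tested and stay open. Of the 10 splits of the 6 arrays into 3 and 3, 1, the real one, gave as many genes, 6161 against a highest of 0 in the others, and 10 splits are too few for a share under 0.05. It stays open whether the differences come from CTCFL or from the separate derivation of the cells in each group, which the design does not part.

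Lower expression along stretches of chromosomes 6, 14 and X may come from a different number of copies of these segments in the 2 groups of cells. When the stretches were sought on every other brighter gene, at least 87.7% of the genes left out of the search were below 0 within them (95% confidence interval 77.9 to 94.2). The search of 1 set also gave 15 genes of chromosome 7 (median -0.15 of 14 left out, 92.9% below 0). The other set and the search of all brighter genes did not give that stretch. Of 1000 shuffled gene orders, 0 gave a run as strong on any of the 3 chromosomes. The search made a cut only where none did, so this outcome was fixed in advance and is no separate test. The weakest stretch, on chromosome 6, kept a median of -0.28 after quantile normalization. Scaling acts on genes by their signal and not by their position, so this could hardly come out otherwise and is no separate test either. The male cells have 1 X, and a median of -0.63 is less than its loss in all cells would give, so a further copy in control cells or a loss in part of the cells are candidate forms. A copy number difference and a regional effect of CTCFL on transcription cannot be told apart, since both lower neighbouring genes and no DNA was analysed here.

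Germ line genes higher in FLAG-CTCFL cells were weighed as well. Germ cells in the culture cannot be told apart from a rise within the ES cells, since 29 of the 57 members of the germ line and meiotic lists outside the stretches rose and 9 fell past the threshold, and a fall of genes that ES cells express leaves room for a small share. For other cell types all 5 list medians met the bound set before against them, the highest at 0.0694. The question is still left open, because members went both ways and the trophoblast list passed as higher with the preset correlation. A general loss of germ line silencing cannot be told apart from a selective one, since 50% of the measured members rose, exactly at the bound set before. A direct action of CTCFL, a germ line protein, stays open as the design's own explanation and was not tested here.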

How the results depend on the processing

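Only the removal of the genes of the stretches was chosen after the result was seen. Ctcfl rose by 3.40 to 3.49 in the settings that refitted it, and the 30 largest changes kept direction and threshold in all 434 values. Changed genes numbered 4950 to 6429 with 1 array left out, 3924 (1458 higher) with the t-test per gene against 6161 (2496 higher), because it shares no variance between genes, and 709 (157 higher, 552 lower) at 1.5-fold by construction. With quantile normalization 3943 were higher and with array weights 4195 of 9204; the cause was not tested. The replicate numbers do not pair the arrays (correlations of same-numbered deviations 0.134, -0.204 and -0.0208, and not every array correlates best with its own number), and the replicate block gave 5979 genes. Lists past the threshold numbered 0 with an estimated correlation, 14 with fry, which tests each list by itself, and 8 to 13 with 1 array left out. Fry put the p53 targets (median 0.0209) lower, against camera, and array weights turned Cdca5 from -0.0024 to 0.11; the cause was not tested. Values of lists and named genes were labelled by the call alone: same where it did not change, weaker where it was lost, stronger where it was gained. Of 493 values of lists 461 were the same, 19 weaker, 12 stronger and 1 reversed, and of 2499 values of 168 named genes 2423, 54, 21 and 1. A list that passed in neither setting counts as the same even where its median changed sign. The architectural list is such a case, at -0.04 with the deposited values and 0.04 after quantile normalization. Without FLAG-CTCFL replicate 3, 9 chromosomes passed against 6 (6 to 9 with 1 array left out), and without the genes of the stretches 1, with chromosome 14 at 0.0034, since those genes made its shift. Signal near the background median of 7.09 limits what can be seen in the dimmest genes.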

Other observations

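Both tests in this part, of gene families and of X linkage, were chosen after the result was seen.

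None of 458 gene families formed from shared symbol stems passed as a set (smallest camera adjusted p = 0.185, with 40 families at an unadjusted p under the threshold).

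X-linked genes were frequent among the genes raised at least 1.5-fold, which is a hypothesis of a preference found and tested on the same data. Of 157 such genes 19 were X-linked (12.1%, against 3.66% of other genes), an odds ratio of 3.63 (95% confidence interval 2.11 to 5.93, Fisher's exact test across genes, p = 6.26e-06), although a stretch of the X was lower. Besides Rhox13, Ct55, Scml2 and Nxf3 they included the kinase gene Pim2 (1.21), Rhox1 (0.98), Cited1 (0.90), Tex16 (0.79), the long non-coding RNA Firre (0.72), Magea5 (0.67), Usp26 (0.64) and Taf7l (0.60). The control mean of Tex16 (7.48) lay within the background range, so its rise is a lower bound. Magea5 lay within that range in both groups (6.89 in control and 7.56 in FLAG-CTCFL arrays), so its rise may lie within the background. Several of these X-linked genes are known from the testis, so the odds ratio may reflect the abundance of testis genes on the X.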
